A study of Mus musculus with 4 samples.

How the data were processed

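Gene expression was measured by RNA sequencing in 4 libraries of cultured mouse spermatogonia (GS cells), 2 from C57BL/6 and 2 from strain 129. The deposited values are raw counts of reads per gene, 1 column per library, for 32285 genes. Per the submitters' processing notes, bcl2fastq 2.20, cutadapt 3.4, HISAT2 2.2.1, HTSeq 0.13.5 and DESeq2 1.30.1 were used with the mouse build mm10, and no settings are given with them. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with a stranded mRNA kit and single reads of 76 bp were sequenced. The annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap on either strand, or that share reads with a near-identical copy, can therefore gain or lose counts. Reads of 129 cells were aligned to a reference built from C57BL/6, which can lose 129 reads at strain variants.

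No row lacked a gene. Chromosomes and positions came from GENCODE release M21 of the same assembly, which holds 32235 of the 32285 gene identifiers (99.85%). Where several identifiers share a symbol, which concerned 38 symbols, the plain symbol stayed with the identifier of the highest count. Each library was assigned to its strain and replicate number from its title. The libraries of a strain were not duplicates: the chi-square per gene between them was 60.6 in B6 and 78.2 in 129. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.957 within B6, 0.968 within 129 and 0.869 to 0.922 between strains. The first principal component held 72.5% of the variance and separated the strains. Mitochondrial genes took 2.31% to 3.09% of the counts.

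From the counts, edgeR 4.0.16 in R 4.3.3 was run with filterByExpr, which kept 16005 genes, TMM factors (0.982 to 1.04), and the robust quasi-likelihood fit and test with strain as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The SE is the absolute log2 fold change divided by the square root of the F statistic, and the biological coefficient of variation was 0.309. CPM use library sizes scaled by TMM. Where a strain had no count, the fold was set against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% counting interval was given. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. With 2 libraries per strain no exact permutation test of a single gene can pass the threshold.

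Before the data were examined, 31 gene lists were fixed, among them markers of fibroblasts, Sertoli, Leydig, endothelial and peritubular muscle cells and macrophages. Of their 709 genes 634 were tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit and has little power. A call lost there need not mean that members vary together. The named genes were also chosen by a rule fixed before the data were examined: the 12 largest folds in each direction among called genes with at least 10 CPM in the higher strain and the libraries of the strains apart, leaving out predicted genes; up to 2 called members per list and direction, or the 2 most abundant where none was called; and 16 genes fixed by name. It named 83 tested genes, of which 52 were called. Pax7, Col1a1 and Dcn in the report and Col3a1 among the later observations fall outside it and were named after their values were seen. Called genes per chromosome were tested with a two-sided Fisher's exact test. Medians per chromosome, with 95% bootstrap intervals from 2000 draws, used genes with a mean of at least 10 CPM and were added after the data were examined.

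The alternatives were DESeq2 size factors, upper-quartile factors, library totals, no filter, a stricter filter, DESeq2 1.42.0, the legacy form of the edgeR test, limma-voom, a replicate block, each library left out in turn, leaving out markers of other cells and mitochondrial genes, and non-robust estimation. A covariate of fibroblast marker expression, with list tests at the preset and at an estimated correlation, was added after the data were examined. The fits were tested on 5 simulated sets for the comparison of 129 against B6, each with 200 changed genes among 15687 to 15738 tested. With the gene by gene spread estimated from these libraries, edgeR recovered 16.0% of genes changed by 1 on the log2 scale, 70.4% of those changed by 2, 89.6% by 3 and 98.4% by 5. Of its calls there 12.7% were false, above the nominal 5%, as were 25.8% for DESeq2 and 10.4% for limma-voom. With the spread on the fitted trend these shares were 6.16%, 17.5% and 5.09%. A list shifted by -0.5 was called lower by camera in 5 of 5 sets under either spread, and 3 and 2 of 150 tests of other lists were called. The simulated genes varied independently of each other. These shares therefore do not cover lists whose members vary together, such as the germ cell and piRNA list, with an estimated correlation of 0.66. In the data 4492 of 16005 genes had an unadjusted edgeR p under 0.05, so more genes may have changed than in the simulated sets. Recovered and false shares depend on how many genes change, and that case was not simulated.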

Results

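The libraries came from GS cells, cultured spermatogonia established from the testes of mice aged 10 days. Total RNA was made into stranded mRNA libraries, and single reads of 76 bp were counted per gene. The study held 4 libraries, 2 from the C57BL/6 strain (B6) and 2 from strain 129. Their totals were 25374801 and 20488618 counts in B6 and 20798809 and 20375086 counts in 129. The comparison asks how gene expression in these cells differs between the strains. Values are CPM, counts scaled to a common library size, given as mean ± SD over n = 2 libraries, and a log2 fold change is 129 over B6 with its standard error (SE). Nothing in the labels says that the 2 libraries of a strain came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

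Agt, F13a1 and Loxl2 were among the genes with the largest strain differences. Agt, which encodes angiotensinogen, had no count in either B6 library and 222 ± 203 CPM in 129, at least 3323-fold higher against a floor of 3 counts over the B6 group. Its 129 libraries stood at 366 and 78.9 CPM, and without 129 replicate 1 the bound was 1186-fold and without 129 replicate 2 it was 5501-fold. F13a1, the A chain of coagulation factor XIII, rose from 0.125 ± 0.107 CPM in B6 to 71.9 ± 14.5 CPM in 129 (log2 fold change 9.02, SE 0.51, edgeR adjusted p = 0.0031). In the other direction, Loxl2, a collagen cross-linking enzyme, was at 151 ± 110 CPM in B6 and 1.58 ± 0.0885 CPM in 129 (log2 fold change -6.58, SE 0.68, edgeR adjusted p = 0.029). Of 16005 genes tested, 457 differed between the strains with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment: 294 were higher and 163 lower in 129, and 448 of them differed at least 2-fold. DESeq2 called 2455 genes and limma-voom 263. Leaving out 129 replicate 2 gave 827 calls, and leaving out 129 replicate 1, B6 replicate 2 or B6 replicate 1 gave 13, 1 or 0 calls, with 2203, 4093 and 3251 genes at an unadjusted p under 0.05. All 457 called genes had both libraries of one strain above both of the other, as had 60.1% of the genes tested, where chance gives 33.3%.

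**Figure D1:**
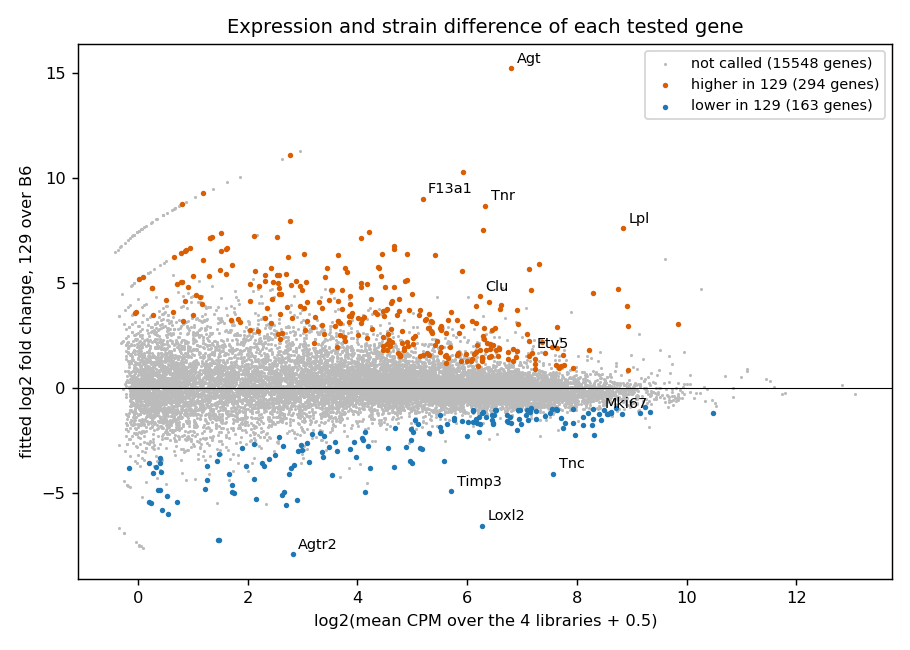
Each point is 1 of the 16005 tested genes, with log2 of its mean CPM plus 0.5 on the x axis and the fitted log2 fold change, 129 over B6, on the y axis. The 294 genes called higher in 129 are orange and the 163 called lower are blue, and fitted values of genes with no count in a strain, such as Agt, depend on the prior count.

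The genes with the largest rise in 129 were often much more abundant in 1 of its libraries. Lpl, lipoprotein lipase, was at 4.59 ± 0.265 CPM in B6 and 911 ± 801 CPM in 129 (log2 fold change 7.63, SE 0.81). Tnr, the matrix protein tenascin R, reached 159.6 ± 108 CPM in 129 from 0.402 ± 0.341 CPM in B6. Il1rn, the interleukin-1 receptor antagonist, reached 155 ± 113 CPM from 0.846 ± 0.344 CPM. Gdpd2 reached 120.4 ± 102 CPM, Npy1r 49.4 ± 32.8 CPM, Krt80 35.7 ± 28.9 CPM and Csf2rb 32.3 ± 22.5 CPM in 129, each from under 1 CPM in B6. Napsa had no count in B6 and was at least 188-fold higher in 129, or 83.4-fold without 129 replicate 1. With 1 to 3 counts in B6, Saa4, a serum amyloid A gene, gave a ratio of 283 (95% counting interval 78.0 to 2345), and Klhl30 gave 157 (53.3 to 763). Without 129 replicate 1 these ratios were 155 and 60.6, and without 129 replicate 2 Napsa's bound was 295-fold and Klhl30's ratio 255. The median log2 ratio of 129 replicate 1 to replicate 2 was 0.81 over the 293 called-higher genes outside the fibroblast list, where it was 1.33 over the fibroblast markers and -0.0048 over all genes tested.

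The largest falls in 129 included Tnc, Timp3, Has2 and Agtr2. Which cells in the cultures these counts came from was not tested. Tnc, the matrix protein tenascin C, was at 358 ± 28.4 CPM in B6 and 21.2 ± 17.3 CPM in 129 (log2 fold change -4.08, SE 0.58, edgeR adjusted p = 0.034). Timp3, an inhibitor of metalloproteinases, fell from 100.4 ± 53.3 to 3.31 ± 1.80 CPM, and Has2, a hyaluronan synthase, from 21.1 ± 3.14 to 1.20 ± 1.23 CPM. Agtr2, a receptor of angiotensin II, was at 13.1 ± 3.28 CPM in B6, with a B6 to 129 ratio of 279 (95% counting interval 76.9 to 2309). Kcne4 fell from 33.3 ± 1.98 to 1.08 ± 0.928 CPM. Aspn, Gdf10, Mfap4, Lemd1, Kif1a and Dkk2 were at 11.0 to 13.6 CPM in B6 and under 1 CPM in 129. Timp3, Aspn and Mfap4 lie over Syn3, Cenpp and Mapk7 on the opposite strand, and the strand setting of the counting is not given in the sources used here.

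Genes of undifferentiated spermatogonia went both ways. Etv5, a transcription factor induced by GDNF, rose from 69.8 ± 14.98 to 218 ± 22.2 CPM in 129 (log2 fold change 1.64, SE 0.22, edgeR adjusted p = 0.032). Cd9, a surface protein used to enrich spermatogonial stem cells, rose from 139 ± 21.5 to 297 ± 10.9 CPM, and Pax7 also rose (log2 fold change 2.50, SE 0.46). Of 32 tested members, edgeR called 3 higher and 0 lower and 29 did not pass, while DESeq2 called 6 higher and 4 lower. Adjusted over the list alone, 5 were higher and 4 lower in edgeR, and the list median was 0.020. The GDNF receptor genes Gfra1 and Ret had log2 fold changes of 0.61 (SE 0.46) and 1.21 (SE 0.41) and did not pass in edgeR, with Ret at 254 ± 152 CPM in B6 and 587 ± 81.4 CPM in 129. Bcl6b (0.66, SE 0.40), Zbtb16 (-0.50, SE 0.24), Id4 (-1.37, SE 0.31) and Nanos2 (-2.13, SE 0.53) did not pass either. In DESeq2, Ret (adjusted p = 0.035), Id4 (adjusted p = 3.8e-04) and Nanos2 (adjusted p = 0.0013) passed.

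**Figure D2:**
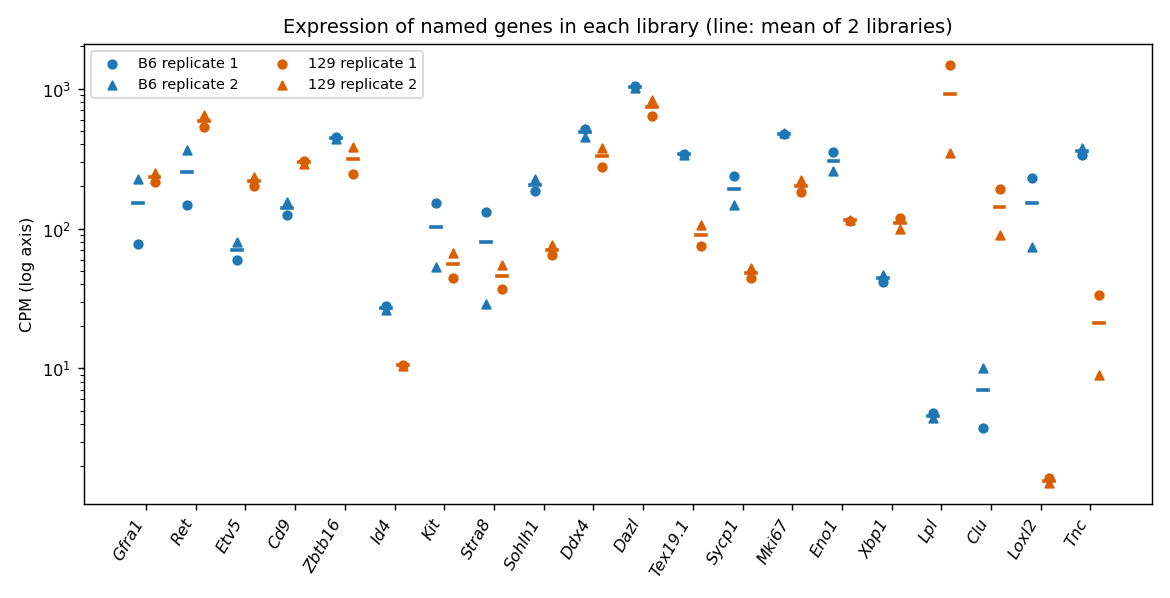
CPM on a log axis of 20 named genes in each library, with B6 in blue, 129 in orange, circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 libraries. Etv5 and Cd9 sit higher in both 129 libraries and Sohlh1, Tex19.1, Sycp1 and Mki67 lower, whereas Gfra1, Kit and Stra8 spread widely between the B6 libraries.

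Genes of germ cell identity and the piRNA pathway, meiosis and differentiating spermatogonia were lower in 129 as lists. In the germ cell and piRNA list, 3 of 25 members fell and 22 did not pass, 7 were lower adjusted over the list alone, and the median was -0.57 (camera adjusted p = 1.2e-05). Tex19.1 fell from 338 ± 6.27 to 90.5 ± 22.6 CPM (log2 fold change -1.90, SE 0.23) and Fkbp6 from 409 ± 17.4 to 179 ± 34.5 CPM, while the germ cell RNA-binding genes Ddx4 (-0.57, SE 0.21) and Dazl (-0.49, SE 0.19) did not pass. In the meiosis list, 2 of 30 members fell, 5 were lower adjusted over the list alone, and the median was -0.43 (camera adjusted p = 0.0031). Sycp1, a component of the synaptonemal complex, fell from 192 ± 64.3 to 48.4 ± 5.66 CPM, and the cohesin subunit gene Stag3 from 543 ± 69.3 to 244 ± 40.4 CPM. In the differentiating spermatogonia list, 2 of 17 members fell, 3 were higher and 5 lower adjusted over the list alone, and the median was -0.47 (camera adjusted p = 0.039). Sohlh1, a transcription factor of spermatogonial differentiation, fell from 206 ± 28.1 to 70.2 ± 7.67 CPM and Crabp1, a retinoic acid-binding protein, from 121 ± 10.7 to 27.8 ± 8.09 CPM, whereas Kit (-0.89, SE 0.49) and Stra8 (-0.81, SE 0.64) did not pass. The haploid germ cell list had 0 calls among 7 tested members by edgeR and 1 by DESeq2, with Odf2 at 0.25 (SE 0.24) and Ldhc at -1.29 (SE 0.44). These 3 calls ended with an estimated correlation (adjusted p = 0.79 for each), as did every other list call. The camera call also ended for differentiating spermatogonia without B6 replicate 1 (median -0.38, adjusted p = 0.38) or 129 replicate 1 (median -0.32, adjusted p = 0.17), and for meiosis without 129 replicate 1 (median -0.25, adjusted p = 0.11), where the 129 libraries lay apart by a list median of -0.49 (log2 ratio of replicate 1 to replicate 2).

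Cell cycle genes were also lower in 129 as a list. Of 37 members 3 fell, 8 were lower and 0 higher adjusted over the list alone, and the median was -0.30 (camera adjusted p = 2.4e-04, and adjusted p = 0.79 with an estimated correlation). The median was -0.47 without B6 replicate 1 and -0.49 without 129 replicate 2. The proliferation marker Mki67 fell from 477 ± 9.38 to 203 ± 28.9 CPM (log2 fold change -1.23, SE 0.18), and the topoisomerase gene Top2a from 796 ± 1.58 to 419 ± 51.7 CPM (-0.93, SE 0.17). The list of cyclin-dependent kinase inhibitors was not called (median 0.59), with Cdkn1a at 1.72 (SE 0.51, edgeR adjusted p = 0.097). Rb1, which the list also holds though it is not such an inhibitor, was at -0.17 (SE 0.22).

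Lists of the GDNF and FGF response, p53 targets and the unfolded protein response were higher in 129. In the GDNF and FGF response list 1 of 22 members, Etv5, rose, 7 were higher and 1 lower adjusted over the list alone, and the median was 0.76 (camera adjusted p = 0.0030). Of 24 p53 targets 2 rose, 11 were higher and 1 lower adjusted over the list alone, with a median of 0.60 (camera adjusted p = 0.0030). Bbc3, which encodes a pro-apoptotic protein, rose from 4.80 ± 0.704 to 18.96 ± 0.859 CPM, and Gdf15 from 0.965 ± 0.454 to 31.7 ± 27.8 CPM. Of 21 unfolded protein response genes 1 rose, 5 were higher and 1 lower adjusted over the list alone, with a median of 0.39 (camera adjusted p = 0.049). Xbp1, a transcription factor of that response, rose from 44.2 ± 3.66 to 109 ± 13.9 CPM. These 3 calls ended with an estimated correlation (adjusted p = 0.79 for each). Without B6 replicate 1 the GDNF and FGF call ended (median 0.59, adjusted p = 0.056), and the unfolded protein response call ended without B6 replicate 1, B6 replicate 2 or 129 replicate 1 (medians 0.61, 0.31 and 0.37, adjusted p = 0.056, 0.19 and 0.36). The immediate early and heat shock list was not called, but was called lower without 129 replicate 1 (median -0.57, adjusted p = 1.6e-05) and higher without 129 replicate 2 (median 0.64, adjusted p = 0.0050). Its median was 0.21 while its camera direction was lower in 129, and Hspa1a, which shares reads with the near-identical Hspa1b, was lower (log2 fold change -2.85, SE 0.44).

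Glycolysis genes were lower in 129 as a list. Of 25 members 2 fell, 6 were lower and 0 higher adjusted over the list alone, and the median was -0.30 (camera adjusted p = 0.014, and adjusted p = 0.79 with an estimated correlation). The enolase gene Eno1 fell from 304 ± 65.1 to 114 ± 2.18 CPM (log2 fold change -1.41, SE 0.21), and Pfkfb3, a regulator of glycolytic flux, from 61.1 ± 41.4 to 8.35 ± 0.0592 CPM. The list call ended without B6 replicate 1 (median -0.16, adjusted p = 0.33) or 129 replicate 2 (median -0.40, adjusted p = 0.072), and the median was -0.81 without B6 replicate 2 and -0.65 without 129 replicate 1. The B6 libraries lay apart by a list median of 0.46 (log2 ratio of replicate 1 to replicate 2). Oxidative phosphorylation had 0 calls among 60 members by edgeR and 2 by DESeq2 (median -0.068), with Cox4i1 at -0.34 (SE 0.18) and Sdha at -0.37 (SE 0.17). The antioxidant list had 0 calls among 29 members by edgeR and 9 by DESeq2 (median 0.39), with Prdx1 at -0.68 (SE 0.17) and Sod1 at -0.15 (SE 0.20). Among cholesterol synthesis genes (median -0.25) Insig1 fell (log2 fold change -1.34, SE 0.22). Without 129 replicate 2 the antioxidant list was called higher (median 0.64, adjusted p = 0.021) and the cholesterol list lower (median -0.39, adjusted p = 0.046). The retinoic acid list (median 0.33), of which Crabp1 is also a member, was not called.

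**Figure D3:**
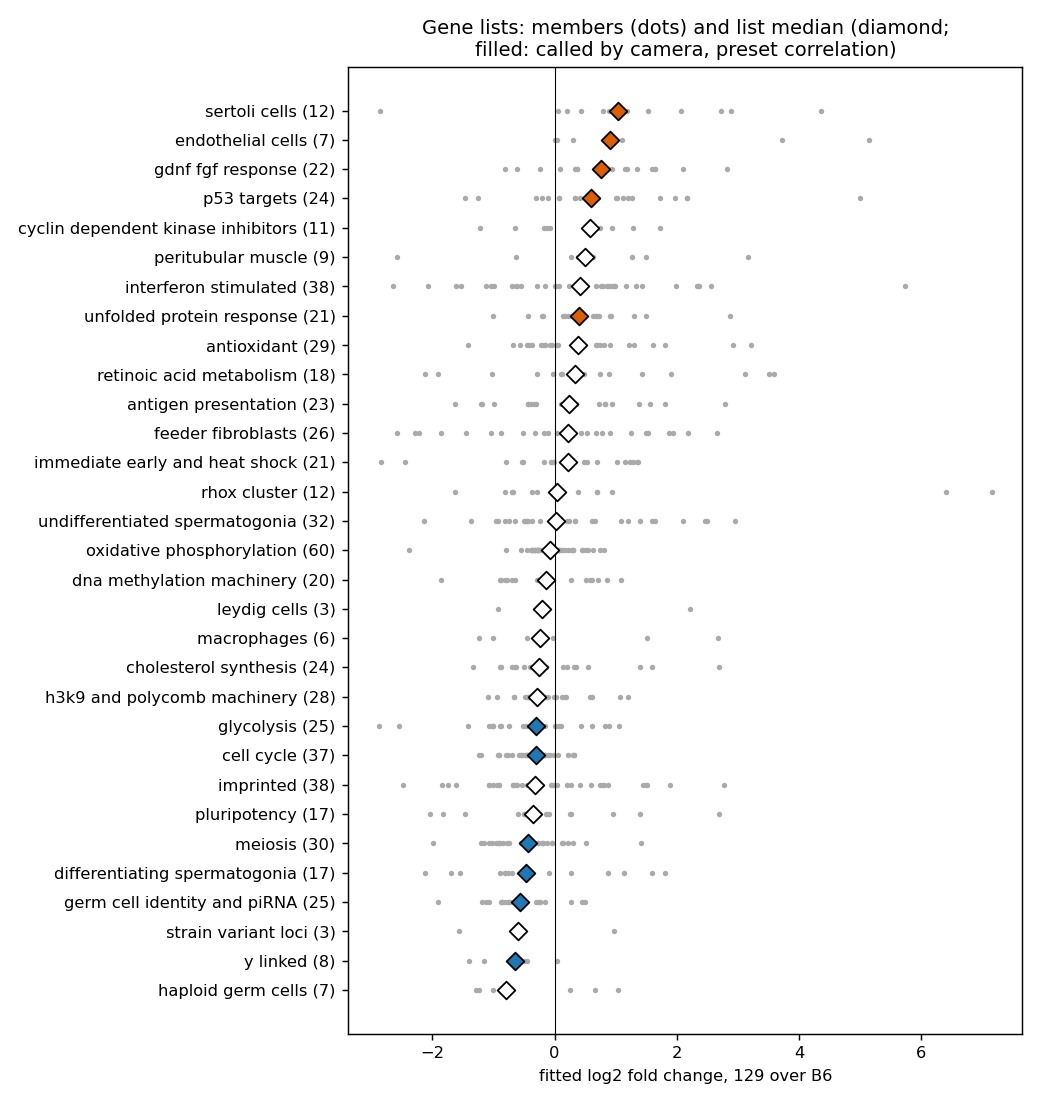
Fitted log2 fold changes, 129 over B6, of the tested members of 31 gene lists (grey dots) with each list's median (diamond), and the number of tested members in brackets. Orange and blue diamonds mark the 5 lists called higher and the 6 called lower in 129 by camera with a preset correlation of 0.01, and white diamonds the others.

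Immune, imprinted and chromatin lists were not called with all 4 libraries. Oas2, an interferon-induced gene, rose from 0.803 ± 0.965 to 40.2 ± 32.0 CPM, 1 call among 38 interferon-stimulated members (list median 0.41), and the list's median log2 ratio of B6 replicate 1 to replicate 2 was -1.35. That list was called lower without B6 replicate 1 (median -0.11, adjusted p = 0.039) and higher without B6 replicate 2 (median 1.28, adjusted p = 4.5e-05). In the antigen presentation list (median 0.24) Erap1, an aminopeptidase gene overlapped by Cast on the opposite strand, fell from 248 ± 21.99 to 125 ± 4.15 CPM. Of 38 imprinted genes (median -0.32) Meg3 fell (log2 fold change -2.47, SE 0.41), as did Peg3 (-1.74, SE 0.30), and adjusted over the list alone 3 were higher and 4 lower. The DNA methylation list (median -0.15) had 0 calls by edgeR and 3 by DESeq2, with Dnmt1 at -0.13 (SE 0.19) and Hells at -0.89 (SE 0.20). The H3K9 and Polycomb list (median -0.28) had 0 calls by edgeR and 4 by DESeq2 and was called lower without 129 replicate 2 (median -0.33, adjusted p = 0.021), with Trim28 at -0.27 (SE 0.16) and Ehmt2 at -0.16 (SE 0.16). In the Rhox cluster (median 0.046) Rhox5 rose from 0.517 ± 0.390 to 42.0 ± 31.9 CPM. In the pluripotency list (median -0.36) Tfcp2l1 fell from 73.1 ± 7.24 to 17.8 ± 3.01 CPM.

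Markers of other cell types moved with strain and within it. The Sertoli cell list (median 1.04, camera adjusted p = 0.018) had 1 rise among 12 tested members, Clu, from 6.96 ± 4.51 to 142 ± 72.6 CPM. The endothelial list (median 0.91, camera adjusted p = 0.015) had 2 rises among 7, Cdh5 from 1.67 ± 1.34 to 57.4 ± 43.1 CPM and Eng, overlapped by Fpgs, from 4.87 ± 0.184 to 64.3 ± 44.8 CPM. Both calls ended with an estimated correlation (camera adjusted p = 0.79). The estimates were -0.058 for the Sertoli and -0.14 for the endothelial list, below the preset 0.01, so members varying together did not end these calls. Without B6 replicate 1 the endothelial median fell to 0.42 and the Sertoli median was 1.81. The fibroblast list was not called (median 0.22, which was -0.77 without 129 replicate 1 and 0.80 without 129 replicate 2, each then called, adjusted p = 3.6e-06 and 7.5e-05), and 7 of its 26 tested members were higher and 5 lower in 129 adjusted over the list alone. Pdgfra, a fibroblast receptor gene, rose from 40.7 ± 2.76 to 149 ± 65.9 CPM, while Col1a1 was at -1.44 (SE 0.45) and Dcn at 1.52 (SE 0.39) without passing over all genes. The list median of the log2 ratio of replicate 1 to replicate 2 was 1.33 in 129 and 0.39 in B6. Des, a muscle filament gene, rose from 2.80 ± 0.0987 to 25.1 ± 5.34 CPM in the peritubular muscle list (median 0.50, and 1.12 without 129 replicate 2, then called, adjusted p = 0.046). The Leydig cell and macrophage lists were not called (medians -0.20 and -0.24, with means of 0.36 and 0.24), with Star at -0.92 (SE 0.44), Fdx1 at -0.20 (SE 0.28), Cd14 at 2.67 (SE 0.64) and Lyz2 at -1.24 (SE 0.54).

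Called genes were unevenly spread over the chromosomes. Chromosome 15 held 33 calls among 664 tested genes, 31 of them higher in 129 (two-sided Fisher's exact test, adjusted p = 0.020). Chromosome 14 held 29 among 555 (adjusted p = 0.020) and chromosome 1 held 42 among 926 (adjusted p = 0.021). Over the 427 genes of chromosome 15 with a mean of at least 10 CPM, 87.8% lay above the median of the other autosomes, and their median relative to it was 0.51 (95% bootstrap interval 0.45 to 0.57). Genes are not independent replicates. Leaving out B6 replicate 1, B6 replicate 2 or 129 replicate 1 left too few called genes to test the enrichment. The Y-linked list was lower in 129 (median -0.64, camera adjusted p = 0.014, and adjusted p = 0.79 with an estimated correlation) with 0 of 8 members called by edgeR, 2 by DESeq2 and 3 lower adjusted over the list alone. That call ended without B6 replicate 1 (median -0.49, adjusted p = 0.072) or 129 replicate 1 (median -0.48, adjusted p = 0.064). Uba1y was at 423 ± 14.6 CPM in B6 and 276 ± 36.6 CPM in 129, and Eif2s3y at 63.3 ± 7.69 and 39.8 ± 6.41 CPM. Of genes known to vary between mouse strains (list median -0.59), Wdfy1, overlapped by Mrpl44 (-0.59, SE 0.27), Casp4 (0.98, SE 0.68) and Disc1 (-1.56, SE 0.54) did not pass, and Nnt and Entpd4 had too few counts to be tested. Nnt is overlapped on the same strand by another entry of the same symbol, so its low counts may not show its expression.

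**Figure D4:**
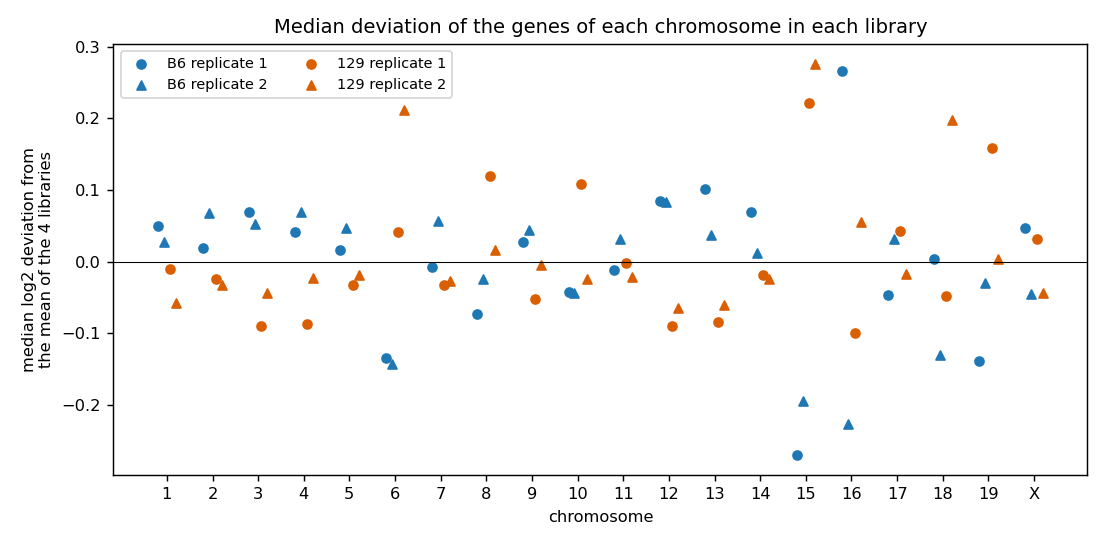
For each chromosome, the median over genes with a mean of at least 10 CPM of the log2 deviation from the mean of the 4 libraries, with B6 in blue, 129 in orange, circles for replicate 1 and triangles for replicate 2. On chromosome 15 the 129 libraries lie at 0.22 and 0.28 and the B6 libraries at -0.27 and -0.20, and on chromosome 16 the B6 libraries lie apart at 0.27 and -0.23.

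In the mouse assembly named in the labels (mm10), Agt (ENSMUSG00000031980) lies on chromosome 8 from 124556534 to 124569706, F13a1 (ENSMUSG00000039109) on chromosome 13 from 36867178 to 37050244, Loxl2 (ENSMUSG00000034205) on chromosome 14 from 69609068 to 69695834 and Etv5 (ENSMUSG00000013089) on chromosome 16 from 22381309 to 22439719. Tnc (ENSMUSG00000028364) lies on chromosome 4 from 63959785 to 64047015, Tex19.1 (ENSMUSG00000039329) on chromosome 11 from 121146143 to 121148319, Sohlh1 (ENSMUSG00000059625) on chromosome 2 from 25842995 to 25847248 and Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361. GENCODE annotates all 8 as protein-coding genes, and the counts are per gene.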

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

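No called gene that was tested changed sign under any alternative listed in the methods, and the fibroblast covariate was chosen after the data were seen. Each called gene had both libraries of a strain above both of the other, so leaving out a library could hardly turn a sign. Against 457 calls (294 higher, 163 lower in 129; 448 at least 2-fold, 290 higher and 158 lower; 31 list members), upper-quartile factors gave 1021 calls (697 and 324; 979 at least 2-fold, 685 and 294; 65 members) and library totals 1052 (746 and 306; 1006 at least 2-fold, 728 and 278; 65 members). Without a filter there were 260 calls (165 and 95), all at least 2-fold, with 19 list members, and with the stricter filter 289 calls, all at least 2-fold, 178 of them higher. DESeq2 gave 2455 (1542 and 913; 2021 at least 2-fold, 1400 and 621; 149 members), sharing 453 of the 457, and limma-voom gave 263 (163 and 100), all at least 2-fold, with 17 members. The fibroblast covariate gave 867 calls (654 higher; 859 at least 2-fold, 652 higher; 61 members), 75.4% of them higher against 64.3%. The fibroblast index came from the same counts. Its list lay at 0.80 in 129 replicate 1 and -0.77 in replicate 2 against the B6 mean, so the covariate can take up spread between the 129 libraries. The cause of the shifts in calls was not tested. DESeq2 size factors, the legacy test, non-robust estimation and leaving out markers of other cells gave 526, 406, 575 and 606 calls. With 2 libraries per strain, the simulated sets left most genes that changed 2-fold uncalled.

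With a replicate block there were 844 calls (623 higher; 840 at least 2-fold, 623 higher; 53 list members). The differentiating spermatogonia and unfolded protein response lists lost their calls (adjusted p = 0.060 and 0.10). The labels do not say that equal replicate numbers mark a shared batch, so the numbers were not taken as pairs. The correlation of same-numbered deviations across genes was -0.0099, and 2 pairs are too few to decide the question.

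Leaving out 1 library, so that a lone library is assumed to vary like the other strain, gave 0 to 827 calls (0 to 750 higher, 0 to 77 lower, the same ranges at least 2-fold), 0 to 63 list members, 0 to 3 enriched chromosomes and 6 to 16 lists. Calls fell to 0 without B6 replicate 1, to 1 without B6 replicate 2 and to 13 without 129 replicate 1, and rose to 827 without 129 replicate 2. Of the 52 named called genes, 0, 1, 7 and 41 were still called, in that order. Against 3 enriched chromosomes, 1 was enriched without a filter, with the stricter filter or with the covariate, and 5 with DESeq2. Against 11 lists, 0 were called with an estimated correlation (smallest adjusted p = 0.79) and 0 with fry (smallest adjusted p = 0.15), and 0 with the covariate and an estimated correlation together (smallest adjusted p = 0.84). The tests with an estimated correlation rest on few residual degrees of freedom, so their lost calls do not decide whether members vary together. The unfolded protein response list also lost its call with DESeq2 size factors, upper-quartile factors, the stricter filter and the covariate (adjusted p = 0.053, 0.051, 0.053 and 0.079), and the Sertoli list with the stricter filter (adjusted p = 0.053). Leaving out a library turned 3 lists that were not called with all libraries, each of them then called in opposite directions: medians ranged from -0.57 to 0.64 for immediate early and heat shock genes (without 129 replicate 1 and 2), from -0.11 to 1.28 for interferon-stimulated genes (without B6 replicate 1 and 2) and from -0.77 to 0.80 for fibroblasts (without 129 replicate 1 and 2). Without 129 replicate 2 the antioxidant and peritubular muscle lists were also called higher (medians 0.64 and 1.12) and the cholesterol synthesis and H3K9 and Polycomb lists lower (-0.39 and -0.33).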

Other observations

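The genes in this paragraph and the next were chosen after their values were seen. Igfbp3, which binds insulin-like growth factors, was at 79.4 and 94.7 CPM in B6 and 7.97 and 7.49 CPM in 129 (log2 fold change -3.49, SE 0.26, edgeR adjusted p = 0.029). Igfbp4 and Igfbp5 rose instead (2.46, SE 0.35, and 2.97, SE 0.35), with 174 and 89.5 CPM and 1139 and 591 CPM in the 129 libraries. Socs3, an inhibitor of cytokine signalling, was at 102 and 115 CPM in B6 and 319 and 316 CPM in 129, while the kinase gene Pim1 fell from 372 and 452 to 98.4 and 77.8 CPM. Tgfb1 and Bmp7 rose (log2 fold changes 2.03, SE 0.29, and 1.63, SE 0.22) and Wnt3 fell (-2.90, SE 0.44), to 2.46 and 4.17 CPM. Bmp4 rose to 33.7 and 13.8 CPM and Fgf7 to 209.6 and 57.1 CPM in the 129 libraries, from at most 10.9 CPM in B6. The Prame family members Pramef12, Pramef8 and Pramel1 fell (-1.67, -1.38 and -1.48), though reads of such related genes can be split between copies.

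Other genes were higher in both 129 libraries and more so in replicate 1. Cxcl12, a chemokine, was at 24.7 and 39.3 CPM in B6 and 1261 and 398 CPM in 129, and the collagenase gene Mmp13 at 30.3 and 21.3 CPM in B6 and 929 and 270.3 CPM in 129. Spp1, osteopontin, rose from 202 and 194 CPM to 2493 and 761 CPM. The serum amyloid gene Saa3 stood at 9.56 and 173 CPM in B6 and 3571 and 1169 CPM in 129 and did not pass (edgeR adjusted p = 0.084). The counts of Gm42418, Lars2 and Gm15564 fell together in 129 (log2 fold changes -1.18, -1.65 and -1.63). Gm42418 is overlapped by AY036118, and Gm15564 by Parp9 and Kpna1, on the opposite strand. Whether these falls reflect expression of the named genes was not tested. Xist, the RNA of the inactive X chromosome, also fell (-3.05, SE 0.57), with 23.2 and 11.7 CPM in B6 and 1.40 and 2.80 CPM in 129.

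In the patterns that follow, the tests of chromosome 15 along its length and over genes that do not follow the fibroblast markers were set before their results were seen, and the other tests after. Genes on chromosome 15 were higher in 129, by a relative median of 0.51 on the log2 scale (1.42-fold), with the 129 libraries at 0.22 and 0.28 and the B6 libraries at -0.27 and -0.20. A gap of 0.49 on chromosome 16 lay between the B6 libraries (0.27 and -0.23), so a shift of this size also stood within a strain, and on chromosome 6 (relative median 0.27) the 129 libraries lay apart, at 0.042 and 0.21. Loss of 129 reads from chromosome 15 on the C57BL/6 reference would lower its genes, against the direction of the 0.51. That follows from the pattern itself and was no separate test. RNA from cells that follow the fibroblast markers between the 129 libraries is argued against by 263 chromosome 15 genes. These lay at or below their replicate 2 level in 129 replicate 1, with a relative median of 0.53 (95% bootstrap interval 0.48 to 0.58). RNA from other cell types stays open. A candidate explanation is more copies of chromosome 15 in the 129 than in the B6 cells, since the shift ran along the whole chromosome. Its lowest median was 0.39 and its highest 0.65 among 4 stretches with about equal numbers of genes. These values are relative, so they do not show in which strain the copies would have changed. A regulatory difference between the strains and a larger loss of 129 reads on the other chromosomes were not tested, and no DNA was measured.

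Genes called higher in 129 often differed between the 129 libraries, with a median log2 ratio of replicate 1 to replicate 2 of 0.81 (95% bootstrap interval 0.60 to 0.97) over the 293 outside the fibroblast list. The fibroblast list's median of 0.22 pools libraries that part, lying 0.80 above the B6 mean in 129 replicate 1 and at -0.77 in replicate 2. More of the same fibroblasts in 129 is argued against by its members, since adjusted over the list alone 7 were higher and above both B6 libraries in both 129 libraries and 5 were lower and below both, with Col1a1 and Col3a1, among its most abundant, at -1.44 and -1.86. RNA from other cells whose share differed between the 129 libraries may contribute and stays open. The median ratio was 1.33 over the fibroblast list, 1.17 over macrophage and 0.70 over peritubular muscle markers. It was 0.088 over the Sertoli and -0.29 over the endothelial list, both called higher in 129, and -0.16 over the Leydig cell list. The called members Clu (Sertoli), Cdh5 and Eng (endothelial) had ratios of 1.09, 1.70 and 1.56, so these medians do not describe the called members. A difference in state or handling between the 129 libraries was not tested apart from such a share, and the ratio over the immediate early and heat shock list was 1.06.

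The germ cell and piRNA list and the cell cycle list had medians of -0.57 and -0.30 in 129, with 3 of 25 and 3 of 37 members called lower by edgeR, and their calls at the preset correlation ended with an estimated one (adjusted p = 0.79 for both); the cell cycle median was -0.47 without B6 replicate 1 and -0.49 without 129 replicate 2. A composition difference that follows the fibroblast markers stays open, since the covariate test could not decide it. The fibroblast list lay 0.80 above the B6 mean in 129 replicate 1 and at -0.77 in replicate 2. A fibroblast index therefore differed little between the strains and could barely move the strain difference, whatever its cause. With that index as a covariate, the germ cell and piRNA list had a median of -0.63 (95% bootstrap interval over its genes, taken as independent, -0.84 to -0.36). Its camera adjusted p was 9.9e-06, and 0.84 with an estimated correlation. The covariate moved the calls over all genes from 457 to 867. In 129 replicate 2, where the fibroblast list lay at -0.77 against the B6 mean, the germ cell and piRNA list lay at -0.41 with 19 of 25 members lower. A smaller share of germ cells in the 129 libraries could lower these genes and stays open: it would lower the undifferentiated spermatogonia list alike, and that list's median lay 0.59 above the germ cell and piRNA list's, but the 95% bootstrap interval of 0.10 to 1.15 reaches below the bound of 0.2, and 6 of its members are also in the GDNF and FGF response list. Among lists of other cells, the Sertoli and endothelial lists were called higher in 129 at the preset correlation (medians 1.04 and 0.91). The fibroblast, peritubular muscle, Leydig cell and macrophage lists were not called (medians 0.22, 0.50, -0.20 and -0.24). A strain difference in the germ cells themselves was not tested apart from a change in their share.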
